A study of Mus musculus with 18 samples.

How the data were processed

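Total RNA from mouse colon was made into stranded mRNA libraries and sequenced as paired reads, per the labels' protocols. The labels give 3 genotypes, 2 drinking conditions and replicate letters A, B and C, which makes 18 libraries in 6 groups of 3. The deposited table holds 1 column of raw read counts per library and 1 line per gene symbol, with 45777 genes, and the authors' values were whole numbers throughout. The submitters' processing notes name FastQC 0.11.7, Trimmomatic 0.38, HISAT2 2.1.0, StringTie 2.1.3b, DESeq2 1.42.1 and R 4.3.2, and they name the builds GRCm38 and mm10, without saying what each tool was set to do. How multiply mapped reads, overlapping genes and strand were counted is not stated. Genes with near-identical copies or overlapping neighbours, such as Ndufs5 and Ndufs5-ps, Il4i1 and Il4i1b, Gsdmc2 and Gsdmc3, Mt1 and Mt2, Trim12a and Trim12c, the kallikrein and haemoglobin genes, Vmn2r29, Gbp8, Ugt1a5 and Apoc2, are therefore uncertain.

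Differential expression was computed from the deposited counts in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr at its default settings, which left 18848 genes. Libraries were scaled with TMM factors, and quasi-likelihood models with robust dispersion were fitted to all 18 libraries at once with 1 mean per group. The 6 groups then shared 1 estimate of the spread. Each comparison was a contrast of group means tested with glmQLFTest, and p-values were adjusted by the Benjamini-Hochberg method within the comparison, with a threshold of 0.05 and no minimum fold. Every adjusted p of a single gene comes from this edgeR test unless another tool is named. Comparisons were the 3 pairs of genotypes under water, under DSS and averaged over the treatments, DSS against water in each genotype and averaged with equal weight over the 3 genotypes, and 2 interactions that set the DSS response of each knockout against that of WT. Standard errors of log2 fold changes were taken as the absolute log2 fold change divided by the square root of the F statistic. CPM values were scaled with the TMM factors and are given as mean ± SD.

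The depth of 26003174 to 36553193 counts per library sets a floor, since a count of 0 allows up to 3 counts, and such limits cover counting error only. Known changes were planted in simulated counts, in 50 genes per fold and only in genes with a mean above 1 CPM. Recovery at lower counts was therefore not measured. The LAO1KO against WT comparison under water recovered 22, 56, 92 and 98% of genes changed by 1.5, 2, 4 and 8-fold, with 18677 genes tested, and 5.52% of its calls were false. The DSS comparison averaged over genotypes recovered 42, 86, 96 and 100%, with 18667 genes tested, and 7.14% of its calls were false. Apart from the planted changes, all simulated libraries were drawn independently around 1 mean per gene, without library-wide shifts. These rates therefore describe the simulated counts and need not hold for the real libraries.

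Single measures per library were compared with 2-sided exact permutation tests, which for 3 libraries against 3 cannot give a p under 0.1. Lao1 had too few counts to pass the filter and was compared only in this way. Mitochondrial mRNA share is the percent of all counts in the 13 mitochondrially encoded mRNAs. The clock index is the mean log2 CPM of genes that peak with Dbp minus that of genes that peak with Arntl.

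Before the data were examined, 41 gene lists, the rule for naming genes, the comparisons and the alternatives not called added below were written down. The 13 mitochondrial genes carry other symbols in the table (ND1, COX1 and so on) and were matched by aliases after the table was seen. A list needed 4 members past the filter, which left 40 lists. Each was tested with camera in limma 3.58.1 with a preset correlation between genes of 0.01, adjusted over the lists within a comparison. Camera with a correlation estimated from the data and fry, a rotation test of whether the genes of a list move on balance in 1 direction, were alternatives.

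Genes were named by the following rule. Lao1 and Il4i1 were always named. For each knockout against WT within a treatment, and for DSS in WT and averaged over genotypes, up to 10 higher and 10 lower genes with the largest changes were named, and up to 5 and 5 for the other comparisons. They needed an adjusted p under 0.05, at least 1 CPM in the higher group and no overlap of CPM between groups, within every stratum for averages. The last condition has no meaning for interactions and was skipped there. Gene models without a proper symbol, pseudogenes and receptor segments were counted and not named. For lists that passed, up to 4 members with the smallest p were named, and for others mainly members that passed. Genes that passed within 1 Mb of Lao1 or Il4i1 were also named, a distance chosen after the data were seen.

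Positions came from the RefSeq annotation of GRCm38.p6. Of the 18848 tested genes 18340 matched by symbol and 133 by synonym, and 375 did not match. Whether genes that passed gathered on chromosome 4 or 7 was tested with Fisher's exact test after the results had been seen, and for other tools among the same tested genes. That test counts genes as independent, which linked genes measured in the same libraries need not be, so its p-values can overstate the evidence. Correlations of log2 fold changes were computed across genes. Comparisons that share WT libraries were set beside 20 simulations of unchanged groups that shared a simulated WT group.

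The alternatives chosen beforehand were DESeq2's scaling in edgeR (RLE), no filter on low counts, DESeq2 1.42.0 in place of edgeR, a fit on only the libraries compared, the replicate letter as a block, each library left out in turn, and for correlations only genes of at least 10 CPM. Alternatives added after the data were seen were leaving out mitochondrial and ribosomal RNA genes, limma voom with a weight per library, leaving out genes of chromosomes 4 and 7, leaving out WT water replicate B and WT DSS replicate C together, and scaling and left-out libraries for the Lao1 and Il4i1 levels. All 18 libraries were used in the results as reported.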

Results

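Messenger RNA was sequenced from whole colon tissue of germ-free male C57BL/6J mice, animals raised without any microbes. The 18 libraries fell into 6 groups of 3, labelled as biological replicates. The 3 genotypes were wild type (WT), libraries labelled LAO1KO (Lao1-/-) and libraries labelled DKO (Lao1-/- Il4i1-/-). Lao1 and Il4i1 encode L-amino acid oxidases, enzymes that deaminate amino acids and release hydrogen peroxide. Each genotype received either normal sterile water or water with 2.5% dextran sulfate sodium (DSS), a detergent-like polysaccharide that injures the colonic epithelium, for 24 hours. The design asks what DSS does at this early time, what loss of Lao1 or of both oxidases does in each drinking condition, and whether the DSS response depends on genotype.

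The libraries held 26003174 to 36553193 counts each, with a mean of 30.8 ± 2.95 M (SD, n = 18). Group means under water were 31.6 ± 1.89 M for WT, 33.5 ± 3.72 M for LAO1KO and 29.2 ± 1.74 M for DKO. Under DSS they were 28.7 ± 1.34 M, 29.1 ± 4.58 M and 32.4 ± 0.169 M in the same order (SD, n = 3 each). Of 45777 genes in the table, 18848 had enough counts to be tested and 15816 had no count in any library. The libraries differed in composition within groups as well as between them. Scores of the adipocyte genes spanned 6.44 log2 units over the 18 libraries, those of B-cell genes 4.46 and those of red-cell genes 3.81. The WT water replicate B stood apart on the main axis of variation at -57.8, with LAO1KO water replicate A at -42.1.

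Lao1 (GRCm38, chromosome 4, 118961967 to 118968910) was close to the floor in every library, so it could not check the LAO1KO label. It had 69 counts in all 18 libraries together and 0 to 10 in any of them. Its mean was 0.0335 ± 0.0598 CPM in WT, 0.162 ± 0.130 in LAO1KO and 0.170 ± 0.123 in DKO over both treatments (SD, n = 6 each). Lao1 was therefore not lower in the knockouts. The 2-sided exact permutation tests within treatments gave p = 0.04 for LAO1KO and 0.045 for DKO against WT, or 0.0675 each after adjustment over the 6 target tests. The labels do not state which exons were deleted, so it is not known whether these few reads lie outside the deleted part.

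Il4i1 was lower in the DKO libraries than in the others, although DKO DSS replicate B came close to LAO1KO DSS replicate C. Il4i1 (chromosome 7, 44836288 to 44840809) and the overlapping gene model Il4i1b (44816370 to 44840804) cannot be told apart at the read level, so their counts were summed. The sum was 1.55 ± 0.754 CPM in WT, 1.24 ± 0.566 in LAO1KO and 0.0605 ± 0.148 in DKO (SD, n = 6 each). It was 0 in 5 of the 6 DKO libraries, where a count of 0 allows up to 3 counts, and 12 counts of Il4i1b remained in DKO DSS replicate B (0.363 CPM). LAO1KO DSS replicate C also held 12 counts (0.491 CPM), so raw counts did not tell these libraries apart. The exact permutation test within treatments gave p = 0.005 for DKO against WT and against LAO1KO, the smallest p that the 400 arrangements allow and 0.015 after adjustment. LAO1KO and WT differed by -0.301 CPM with an exact permutation p of 0.47, or 0.564 after adjustment. In edgeR's test neither Il4i1b (log2 fold change -5.65 ± 1.27, SE; adjusted p = 0.0841) nor Il4i1 (adjusted p = 0.426) passed for DKO against WT over both treatments.

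**Figure D1:**
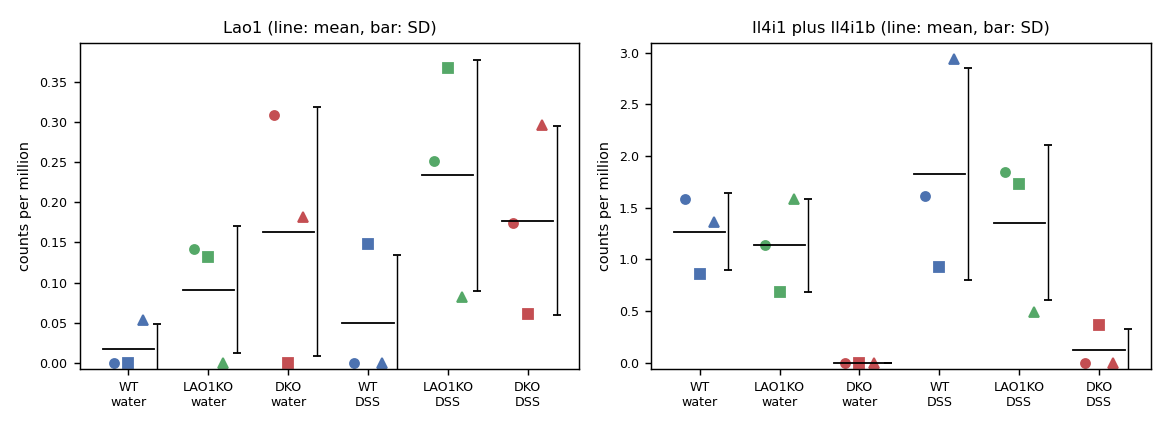
Normalised level in CPM of Lao1 and of Il4i1 plus Il4i1b in each of the 18 libraries by group, with group means and SD and replicates A, B and C as circles, squares and triangles. Lao1 stayed below 1 CPM in every library, and the Il4i1 sum was at 0 in 5 of the 6 DKO libraries.

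Averaged over the 3 genotypes, circadian clock genes differed between mice given DSS for 24 hours and mice on water, and 5 of the 10 largest named increases were among them. The labels give no time of collection. The clock-output factors Dbp (log2 fold change 2.04 ± 0.21, SE; edgeR adjusted p = 1.29e-04) and Hlf (1.27 ± 0.16; 2.17e-04) rose. So did the clock repressors Bhlhe41 (2.11 ± 0.32; 6.44e-04), Ciart (1.68 ± 0.25; 7.65e-04) and Per3 (1.17 ± 0.25; 0.00785). The activators Arntl (-1.28 ± 0.10; 5.19e-06) and Npas2 (-1.04 ± 0.10; 2.37e-05) fell. Dbp went from 9.83 ± 3.79 to 117 ± 12.4 CPM in WT, from 26.3 ± 14.6 to 80.4 ± 8.34 in LAO1KO and from 27.0 ± 4.23 to 51.5 ± 3.16 in DKO (SD, n = 3 each). Of the 16 clock genes tested, 8 rose and 4 fell, or 9 and 4 when adjusted over the list alone. A list that moves both ways gave camera adjusted p = 0.0539, and 0.552 with an estimated correlation.

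The metallothioneins Mt2 (1.35 ± 0.15; edgeR adjusted p = 1.29e-04) and Mt1 (1.12 ± 0.16; 6.34e-04), which bind zinc, also rose. The gasdermins Gsdmc2 (1.13 ± 0.16; 5.34e-04) and Gsdmc3 (1.12 ± 0.18; 0.00122) rose with them. Both pairs are close paralogs whose reads the counting could share. Among cytokines and chemokines 4 of 14 tested genes rose and 1 fell, or 6 and 1 when adjusted over the list alone, with camera adjusted p = 0.14. Cxcl10, a chemokine that draws T cells, rose by 1.20 ± 0.28 (adjusted p = 0.0091) and Tnf by 1.01 ± 0.27 (0.0193), while Tnfaip3, a brake on NF-kappa-B signalling, fell by 0.56 ± 0.10 (0.00189). Tnf stayed low, at 2.06 ± 0.553 CPM in WT under DSS against 0.941 ± 0.546 under water. Il1b was between 0.336 and 0.537 CPM in every group mean.

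Sgk1, a kinase that promotes sodium uptake, fell by 1.37 ± 0.14 (edgeR adjusted p = 6.29e-05), and the claudin Cldn8 by 1.10 ± 0.12 (6.29e-05). Of the 17 tight junction and adhesion genes 7 fell and 0 rose, or 9 and 0 when adjusted over the list alone, among them Ocln, Cldn15 and Marveld3. The list had camera adjusted p = 1.46e-05, and 0.527 with an estimated correlation. Of 15 absorptive colonocyte genes 6 fell and 0 rose, or 6 and 1 when adjusted over the list alone. They included the sulfate transporter Slc26a2 (-0.94), Muc3 (-0.77) and Cyp2c55 (-0.77), and the list had camera adjusted p = 0.0023, and 0.552 with an estimated correlation. Goblet cell genes went both ways, with 6 of 14 higher, such as Bcas1 (0.51), Tff3 (0.80), Fcgbp (0.77), Clca1 (0.74) and Zg16 (0.66), and 2 lower. Their median was -0.09 while the camera direction was up, at adjusted p = 0.0797. Other large decreases were Trpa1 (-1.42 ± 0.29; 0.0042), Igsf10, Taco1, the glycogen branching enzyme Gbe1 and the epithelial kinase Ptk6, each between -1.08 and -1.02.

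Of 16 unfolded protein response genes 9 fell and 0 rose, or 10 and 0 when adjusted over the list alone. The endoplasmic reticulum chaperone Hspa5 fell by 0.51 ± 0.12 (edgeR adjusted p = 0.0079), with Dnajc3 (-0.51), Dnajb11 (-0.42) and Edem1 (-0.35). The list had camera adjusted p = 9.30e-06, and 0.552 with an estimated correlation. Of 12 heat shock genes 6 fell and 0 rose, the same numbers as when adjusted over the list alone. They were led by Hsph1 (-0.81), Hspd1 (-0.54), Dnaja1 (-0.48) and Hsp90aa1 (-0.37), with camera adjusted p = 2.11e-05, and 0.588 with an estimated correlation. Of 23 cell cycle genes 4 fell and 0 rose, namely Mcm5 (-0.60), Rrm2 (-0.51), Mcm6 (-0.38) and Pcna (-0.36), or 7 and 0 when adjusted over the list alone. That list had camera adjusted p = 0.00652, and 0.909 with an estimated correlation, and without LAO1KO water replicate A its camera adjusted p was 0.0926.

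Of 15 enteric neuron and glia genes 10 rose and 0 fell, or 12 and 0 when adjusted over the list alone. The former were led by the neuronal tubulin Tubb3 (0.89), Uchl1 (0.80), Snap25 (0.78) and Prph (0.76), and the list had camera adjusted p = 5.36e-07, and 0.588 with an estimated correlation. All 13 mitochondrially encoded mRNAs rose, 13 of 13 also when adjusted over the list alone, with ND1 at 1.33, ND2 at 1.30, COX3 at 1.10 and ND3 at 1.05. That list had camera adjusted p = 7.11e-21, and 0.437 with an estimated correlation. The share of counts from mitochondrial mRNA was 7.87 ± 1.11% in WT, 12.2 ± 3.06% in LAO1KO and 15.7 ± 5.10% in DKO under water (SD, n = 3 each). Under DSS it was 32.7 ± 10.6%, 19.2 ± 3.76% and 19.5 ± 4.78%. The 2-sided exact permutation test within genotypes gave a difference of 11.9 percentage points with p = 0.00275, where the smallest p that the 8000 arrangements allow is 0.00025. Within single genotypes it was 24.8 points in WT and 7.06 in LAO1KO (exact permutation p = 0.1 each, the smallest possible) and 3.81 in DKO (exact permutation p = 0.5). WT DSS replicate C had the highest share, 44.9%, and the lowest scaling factor, 0.625. Ribosomal RNA made up 0.853 to 6.50% of counts.

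Counting all genes, 2996 differed between DSS and water on average over genotypes, 1266 higher and 1730 lower under DSS. Of these, 208 changed by more than 2-fold and 2107 by less than 1.5-fold. The clock index was at most -0.0996 in the water libraries and at least 0.496 in the DSS libraries. With no collection time given, a difference in time of day cannot be told apart from DSS for any of these genes. The 20 genes named by size all passed in each of the 18 fits that left out 1 library. Without DKO DSS replicate B the count was 1928.

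**Figure D2:**
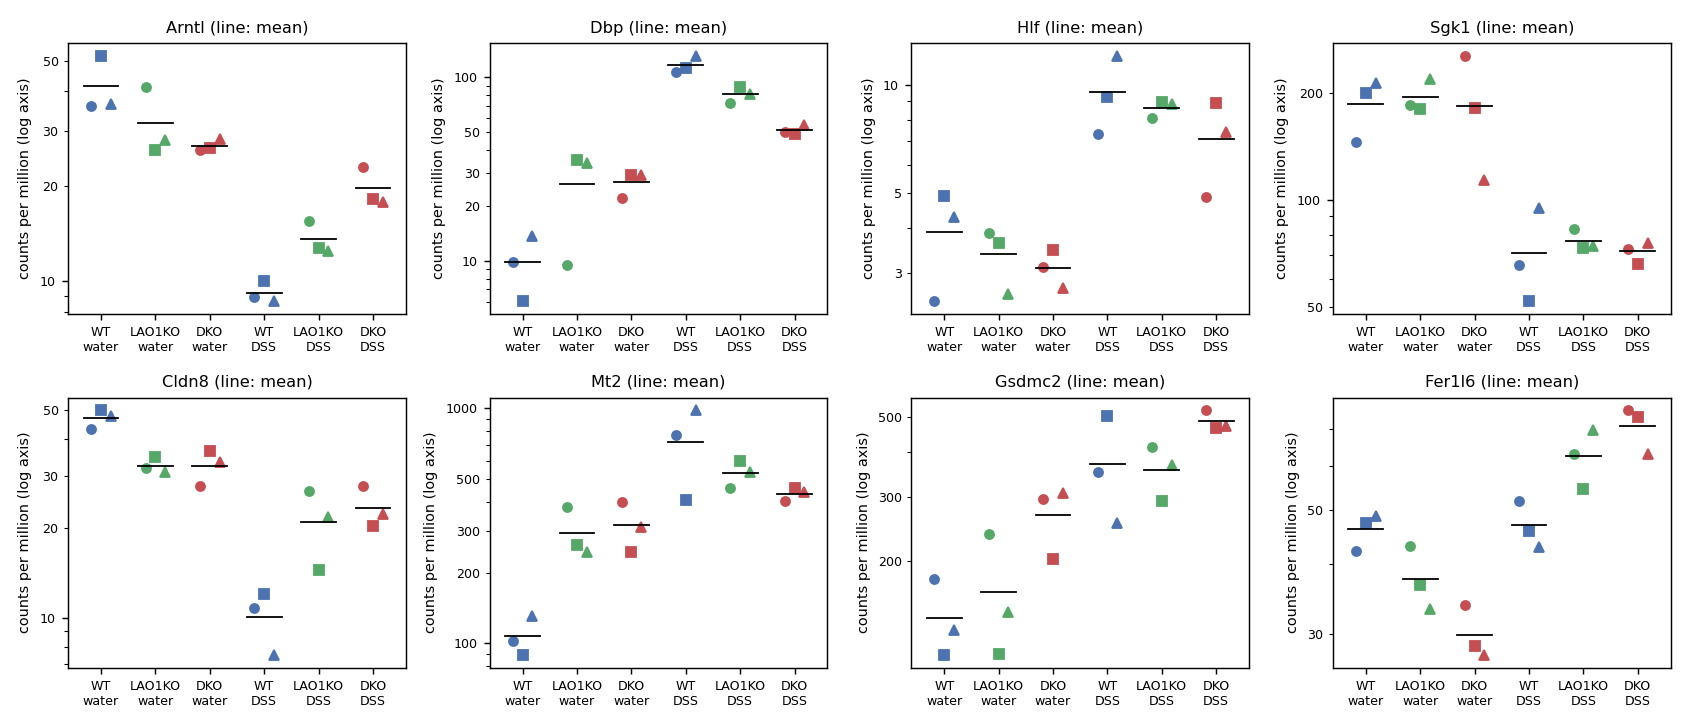
Normalised level in CPM, on a log axis, of genes named for the DSS response, in each of the 18 libraries by group, with group means as lines and replicates A, B and C as circles, squares and triangles. Dbp and Mt2 lay higher and Arntl, Sgk1 and Cldn8 lower under DSS in every genotype.

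**Figure D3:**
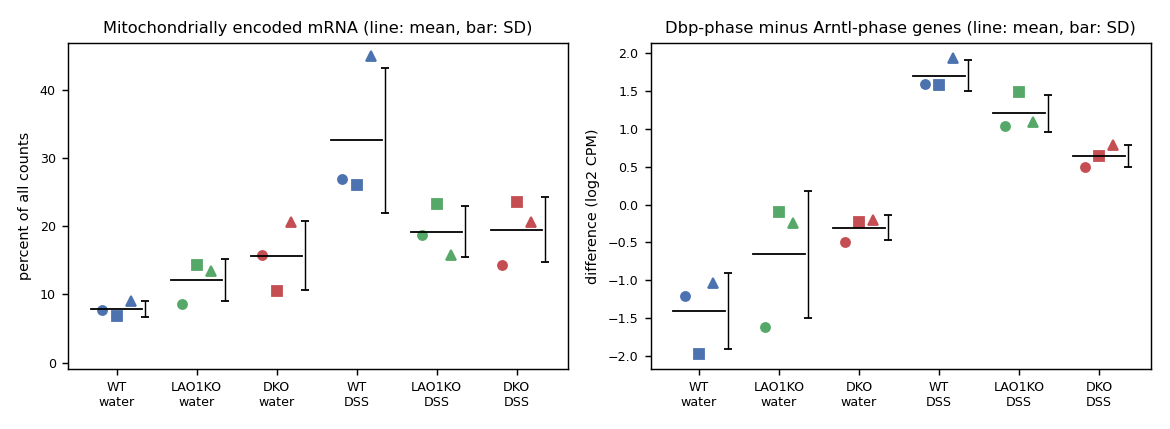
Share of counts from mitochondrially encoded mRNA in percent, and clock index in log2 units (mean log2 CPM of Dbp-phase genes minus that of Arntl-phase genes), for each library by group with group means and SD. The mean share under DSS was 32.7% in WT, 19.2% in LAO1KO and 19.5% in DKO.

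In WT mice alone Dbp rose by 3.57 ± 0.39 (SE; edgeR adjusted p = 3.65e-04), Ciart by 3.43 ± 0.47 (9.99e-04) and Mt2 by 2.75 ± 0.28 (1.04e-04). Mitochondrial mRNAs filled 4 of the 10 largest named increases, with ND4L at 3.22, ND5 at 3.01, ND4 at 2.80 and CYTB at 2.78. The others were Ugt1a5 (3.18), a glucuronosyltransferase from a locus of overlapping isoforms, Gp1bb (3.09) and the acute-phase gene Saa3 (3.46). The immunoproteasome genes Psmb8 (1.48) and Psmb9 (1.20) and the ubiquitin-like Ubd (2.29) rose as 3 of 20 interferon gamma response genes, also 3 when adjusted over the list alone. Of 14 fibroblast and matrix genes 6 fell, or 7 when adjusted over the list alone, with camera adjusted p = 2.03e-04, and 0.853 with an estimated correlation. Their median of -0.71 was -0.47 without WT DSS replicate A, and WT water replicate B had the highest score of the 18 libraries for this list (6.44 as mean log2 CPM). Across 17228 nuclear genes the WT log2 fold changes fell with transcript length at a Spearman rho of -0.284. The largest named decreases were Slc6a11 (-3.83), a GABA transporter, the retinol dehydrogenase Dhrs9 (-3.60), the glycosyltransferases B3gnt7 (-3.33) and B3galt5 (-2.31), the secretory-cell factor Bhlha15 (-2.62), Adamts4 (-2.43), Zbtb16 (-2.42), Ccn3 (-2.40) and Megf9 (-2.32). The hindgut homeobox gene Hoxa13 had a log2 fold change of -4.81, and the WT water libraries held 39, 602 and 22 of its counts.

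The WT comparison called 2428 genes, 1186 higher and 1242 lower, and leaned on single libraries. Without WT water replicate B it called 777, without WT DSS replicate C 981, without WT water replicate A 1283 and without WT DSS replicate A 1602. Of its 20 named genes 15 passed in all 6 fits that left out 1 library. Without WT DSS replicate C, Saa3 dropped from 3.46 to 1.53 and no longer passed, as was also so without either WT water replicate A or B, and Slc6a11 was lost without WT DSS replicate C or WT water replicate B. Without WT water replicate B, Hoxa13 was -1.78, B3gnt7 -2.11 and Bhlha15 -2.04, and none of the 3 passed. Hoxa13 also failed without WT DSS replicate A (-4.67), B (-5.94) or C (-4.33).

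In LAO1KO mice the named genes that fell under DSS were Sgk1 (-1.34 ± 0.24; edgeR adjusted p = 0.0351), Arntl (-1.22 ± 0.18; 0.014), the magnesium channel Trpm6 (-1.15 ± 0.19; 0.0247), Stk17b (-1.11) and the adrenergic receptor Adra2a (-1.09). The 1 gene that rose was Fer1l6 (0.73 ± 0.13; 0.0351), a membrane-fusion protein of the ferlin family. Of 37 genes that passed, 36 were lower. Heat shock genes had 1 of 12 lower, or 6 when adjusted over the list alone, with camera adjusted p = 1.32e-06, and 0.706 with an estimated correlation. The count was 346 without LAO1KO DSS replicate C, 84 without LAO1KO water replicate A, 9 without water replicate B, 6 without water replicate C, 3 without DSS replicate A and 1 without DSS replicate B. None of the 6 named genes passed in all 6 of those fits.

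In DKO mice edgeR passed 3 genes as higher and 0 as lower under DSS, against 1807 with an unadjusted p under 0.05, 181 in DESeq2 and 478 in limma voom. Fer1l6 rose by 1.24 ± 0.13 (edgeR adjusted p = 5.84e-04), from 29.9 ± 3.44 to 70.8 ± 6.80 CPM, and passed in every fit that left out 1 library. Bcas1, a goblet cell gene, rose by 0.85 ± 0.12 (0.015) but passed in only 1 of those 6 fits, and the third was an unnamed gene model. The count was 1 without DKO water replicate B and without DKO DSS replicate A, B or C. Of 14 goblet cell genes 1 rose, or 6 when adjusted over the list alone, with Fcgbp at 1.31 (adjusted p = 0.0777) and Clca1 at 1.28 (0.117) beside it. The list had camera adjusted p = 3.61e-09, and 0.53 with an estimated correlation.

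Whether the DSS response differed by genotype was tested as an interaction. For DKO against WT 11 genes passed, with edgeR adjusted p between 0.0328 and 0.0452. The DSS decrease of Arntl (interaction 1.72 ± 0.25, SE) and of Cldn8 (1.74 ± 0.28) was smaller in DKO, and so was the increase of Mt2 (-2.31 ± 0.38). Under water Mt2 lay between 88.6 and 130 CPM in WT libraries and between 244 and 401 in DKO libraries. Under DSS it lay between 407 and 986 in WT and between 402 and 459 in DKO. Part of its interaction therefore lay in the higher DKO level under water. Itpkb, an inositol trisphosphate kinase, had an interaction of 2.45 ± 0.38, and its level went from 22.9 ± 2.82 to 4.99 ± 2.65 CPM in WT and from 18.7 ± 4.31 to 22.7 ± 3.61 in DKO. Npy4r (3.16), Hr (1.22), the MHC class I light chain B2m (-1.36) and the near-identical Trim12a (-1.22) and Trim12c (-1.10) completed the named genes. None of the 9 named genes passed in all 12 fits that left out 1 library. The count was 148 without WT water replicate C, 69 without WT DSS replicate B, 18 without DKO water replicate B and 1 without WT DSS replicate A. It was 0 in the 8 fits without WT water replicate A or B, WT DSS replicate C, DKO water replicate A or C, or DKO DSS replicate A, B or C.

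For LAO1KO against WT the interaction test in edgeR passed 0 genes, against 3005 with an unadjusted p under 0.05, 438 in DESeq2 and 2324 in limma voom with library weights. Itpkb was nearest among the genes above, at 2.62 ± 0.38 with edgeR adjusted p = 0.0561. Without WT water replicate C 47 genes passed, without WT DSS replicate B 10, without LAO1KO water replicate A 3, without LAO1KO water replicate B 2 and without LAO1KO DSS replicate B 1. A gene that passed in WT but not in a knockout was therefore not shown to respond differently unless it is among the 11 above.

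Between the libraries labelled LAO1KO and WT, 10 genes passed under water and 16 under DSS, and 5 of them passed in both with the same sign. Over both treatments the proprotein convertase Pcsk5 was higher (1.41 ± 0.10; edgeR adjusted p = 2.55e-07). The rhomboid protease Rhbdl2 (-2.42 ± 0.19; 1.50e-06), the transcriptional regulator Mier3 (-2.02 ± 0.16; 1.50e-06) and the complex I subunit Ndufs5 (-1.95 ± 0.21; 1.66e-04) were lower. Under water Pcsk5 averaged 63.5 CPM in LAO1KO against 23.7 in WT, and Mier3 24.6 against 132. Ndufs5 has a processed copy, Ndufs5-ps, which moved the other way, from 2.62 CPM in WT to 152 in LAO1KO under water, so the assignment of their reads is uncertain. Cfap57 (2.06 ± 0.40; 0.0496), Zfp69 (1.03), Osbpl1a (0.46) and the kallikrein gene Klk1b22 also passed. Klk1b22 belongs to a family of near-identical copies and was at 0.0637 CPM in WT and 7.27 ± 7.87 in LAO1KO under water. Pcsk5, Mier3, Ndufs5 and Rhbdl2 passed in all 12 fits that left out 1 library, and the other 4 named genes did not.

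Over both treatments 25 genes passed, 10 higher and 15 lower, and 904 had an unadjusted p under 0.05 where chance gives 942. Of the 25, 7 lay on chromosome 4, the chromosome of Lao1, which holds 6.21% of tested genes (Fisher's exact p = 6.23e-04, adjusted p = 0.00196). Of those 7, 4 lay between 120 and 130 Mb, the stretch that begins just beyond Lao1. Such genes may reflect DNA inherited with the Lao1 allele rather than loss of Lao1, which was not tested. Under water 10 genes passed and 2690 had an unadjusted p under 0.05, with Cables1 (0.93) higher and the isoleucyl-tRNA synthetase Iars (-0.70) lower beside Pcsk5, Rhbdl2 and Mier3. Cables1 and Iars were each lost in 5 of the 6 fits that left out 1 library. The water count was 105 without WT replicate C, 17 without WT replicate B, 5 without WT replicate A, 6 without LAO1KO replicate B and 5 without LAO1KO replicate C. Under DSS 16 genes passed and 1135 had an unadjusted p under 0.05, and Itpkb was higher by 2.37 ± 0.28 (edgeR adjusted p = 9.24e-04) with all 5 named genes kept in every such fit. That count was 9 without LAO1KO replicate A and 10 without LAO1KO replicate B.

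No fixed list had a member that passed over all genes in these comparisons. Under DSS the 13 mitochondrial mRNAs had a median of -1.21 in LAO1KO against WT, 13 of 13 lower when adjusted over the list alone, with camera adjusted p = 1.08e-18, and 0.565 with an estimated correlation. Their share in WT DSS replicate C was the highest of all, and without that library the median was -0.58. Under water cell cycle genes had a median of -0.53, 8 of 23 lower when adjusted over the list alone (camera adjusted p = 5.88e-09; 0.776 with an estimated correlation). Fibroblast and matrix genes had a median of -0.61 in the same comparison, 2 of 14 lower when adjusted over the list alone (5.37e-06; 0.776 with an estimated correlation), which was -0.96 without LAO1KO water replicate A and -0.40 without LAO1KO water replicate C. Its log2 fold changes across 17228 nuclear genes fell with transcript length at a Spearman rho of -0.296. Amino acid response genes, targets of ATF4, had a median of -0.59, 10 of 18 lower and 1 higher when adjusted over the list alone (3.60e-05; 0.776 with an estimated correlation). That median was -0.34 and the camera adjusted p 0.203 without WT water replicate B. Asns, their asparagine synthetase, was at 33.0 ± 19.4 CPM in WT and 16.7 ± 3.85 in LAO1KO. Type I interferon genes had a median of -0.69 over both treatments, 0 of 26 passing over all genes or when adjusted over the list alone (3.03e-13; 0.548 with an estimated correlation). The interferon median was -0.29 without WT water replicate B (camera adjusted p = 2.82e-06), and under water alone it went from -0.74 to 0.0260 (0.935). That library had the highest score of the 18 for the cell cycle (5.27), ATF4 target (4.18) and type I interferon genes (4.85), each as mean log2 CPM. Red-cell genes had a median of 1.09 over both treatments, 5 of 5 higher when adjusted over the list alone (1.05e-05; 0.548 with an estimated correlation), with Hbb-bs ranging from 27.2 to 132 CPM between group means.

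Between DKO and WT more genes passed than between LAO1KO and WT, 106 against 25 over both treatments, with a median absolute log2 fold change of 1.28 against 2.02, and a block of them lay on chromosome 7, which carries Il4i1. Over both treatments Hddc3, a hydrolase gene, was higher by 2.36 ± 0.11 (edgeR adjusted p = 3.89e-10) and Igsf23 by 3.15 ± 0.18 (1.26e-08). Ntn5 was higher by 3.0 ± 0.36 (1.37e-04), and Apoc2, whose product activates lipoprotein lipase and whose gene overlaps Apoc4, by 2.81 ± 0.42 (0.00233). Klk1b22, within 1 Mb of Il4i1, had a mean of 17.9 CPM in DKO and 0.0637 in WT under water. The unconventional myosin Myo7a (-2.86 ± 0.19; 1.08e-07), Rhbdl2 (-2.70 ± 0.19; 1.99e-07), Vmn2r29 (-2.21 ± 0.24; 5.22e-05), Mier3 (-2.18 ± 0.16; 3.38e-07) and Ndufs5 (-2.17 ± 0.21; 2.17e-05) were lower. Hddc3 averaged 33.6 ± 3.28 CPM in DKO against 6.46 in WT under water, and 34.1 ± 2.20 against 6.76 under DSS. Near Il4i1, Tbc1d17, which overlaps its end, was at -1.21 ± 0.17 (8.25e-04). Ccdc30, also named by the rule, passed over both treatments but was lost in 10 of the 12 fits that left out 1 library.

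Under water 117 genes passed, 70 higher and 47 lower. Named genes not yet given were Abhd3 (2.33), Gbp8 (1.77), Ttc39c (1.69), the sulfotransferase Chst8 (1.62) and Zfp677 (1.61) on the higher side. On the lower side were the secreted phospholipase Pla2g2f (-2.90), the interferon-induced Mx2 (-2.57), Npy4r (-2.52), the glutamine transporter Slc1a5 (-1.60) and Nt5dc2 (-1.60). The peptide hormone gene Guca2b, within 1 Mb of Lao1, was higher by 1.17 ± 0.25 (edgeR adjusted p = 0.0458). Of 23 named genes 10 passed in all 6 fits that left out 1 library, namely Chst8, Hddc3, Igsf23, Ntn5, Mier3, Myo7a, Ndufs5, Npy4r, Rhbdl2 and Slc1a5. The count was 387 without WT replicate C, 50 without WT replicate B, 30 without WT replicate A, 43 without DKO replicate A and 32 without DKO replicate C.

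Under DSS 48 genes passed, 21 higher and 27 lower. Itpkb (2.16 ± 0.28; edgeR adjusted p = 0.00109), Pcsk5 (1.29 ± 0.14; 6.54e-05), Cldn8 (1.21 ± 0.20; 0.00913) and the tyrosine-breakdown enzyme Fah (1.52 ± 0.23; 0.0037) were higher, with Pnmal2 (1.32) and Mill2 (1.16). Slc1a5 (-1.74 ± 0.19; 8.24e-05), Nlrp9b (-1.39), Zfp772 (-1.09) and the colonocyte adhesion gene Ceacam20 (-0.99) were lower. Of 21 named genes 15 passed in all 6 fits that left out 1 library. Chst8, Pnmal2 and Tbc1d17 were lost in all 6, Ntn5 in 4, Cldn8 without WT replicate C or DKO replicate A and Zfp772 without DKO replicate A or C. The count was 29 without WT replicate C, 24 without DKO replicate A, 27 without DKO replicate B and 28 without DKO replicate C. In both treatments 30 genes passed, all with the same sign. Of the 117 water calls 80 had the same sign under DSS, and of the 48 DSS calls 42 had the same sign under water.

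Over both treatments 106 genes passed, 58 higher and 48 lower, and 52 of them lay on chromosome 7, which holds 7.42% of tested genes (Fisher's exact p = 9.14e-31). On chromosome 4 there were 14 (Fisher's exact p = 0.00696, adjusted p = 0.0192). Only these chromosomes were tested for gathering. Chromosome 18, which carries neither targeted gene, had 7 of 497 tested genes passing, or 1.41%, against 1.20% of the 1170 on chromosome 4. Of those 7, 5 lay between 10 and 20 Mb. Among fixed lists, 1 of 17 tryptophan, phenylalanine and tyrosine catabolism genes was higher, Fah (1.54 ± 0.16; edgeR adjusted p = 3.45e-05), also 1 when adjusted over the list alone, with camera adjusted p = 0.156 and fry adjusted p = 0.0426. Fah itself lies on chromosome 7. Of 26 type I interferon genes 1 was lower, Mx2 (-1.82 ± 0.34; 0.0146), or 2 when adjusted over the list alone (camera adjusted p = 3.84e-06; 0.766 with an estimated correlation), and the list's median of -0.65 was -0.19 without WT water replicate B (camera adjusted p = 0.0300). Under water fibroblast and matrix genes had a median of -0.96, 9 of 14 lower when adjusted over the list alone and 0 over all genes (4.85e-09; 0.616 with an estimated correlation), with WT water replicate B the highest library for that list (6.44). Mitochondrial mRNAs were 13 of 13 higher under water when adjusted over the list alone (median 1.12; 1.07e-09; 0.616 with an estimated correlation) and 12 of 13 lower under DSS (median -1.15; 8.68e-16; 0.701 with an estimated correlation), with 0 passing over all genes either way. Without WT DSS replicate C the DSS median was -0.60.

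Between DKO and LAO1KO libraries, which differ by the labels only in Il4i1, most genes that passed in edgeR lay on chromosome 7. Over both treatments Apoc2 (3.14 ± 0.42; edgeR adjusted p = 0.00185), Igsf23 (2.96 ± 0.18; 3.94e-08), Hddc3 (2.29 ± 0.11; 1.13e-09), Chst8 (1.38 ± 0.18; 0.00104) and Fah (1.27 ± 0.16; 6.52e-04) were higher in DKO. Myo7a (-2.91 ± 0.19; 1.12e-07), Vmn2r29 (-2.48 ± 0.24; 2.67e-05), Slc1a5 (-1.75 ± 0.13; 7.04e-07), Ccdc114 (-1.32) and Zfp772 (-1.17) were lower. Ccdc114 was lost in 9 of the 12 fits that left out 1 library. Slc1a5 averaged 73.3 CPM in DKO against 224 in LAO1KO under water, and 69.7 against 259 under DSS. Of 45 genes that passed, 42 lay on chromosome 7, between 7.20 and 98.7 Mb (Fisher's exact p = 2.34e-44, adjusted p = 5.16e-43). Of these, 3 lay within 1 Mb of Il4i1, and the median distance was 25.2 Mb. Because Fisher's test counts linked genes as independent, its p can overstate the evidence. The share on chromosome 7 depended on the tool, with 71 of 90 genes in DESeq2 and 127 of 352 in limma voom with library weights (Fisher's exact p = 4.39e-63 and 8.49e-55). The 3 others, named after their values were seen, were Hebp1 on chromosome 6 (-1.15; adjusted p = 0.0310), Gm33272 and LOC115486508.

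Under water all 15 genes that passed in edgeR lay on chromosome 7, and under DSS all 12. In DESeq2 33 of 48 and 24 of 26 did, and in limma voom 26 of 32 under water but 263 of 2530, or 10.4%, under DSS (Fisher's exact p = 4.90e-09). In edgeR 9 genes passed in both treatments. All 15 water calls and all 12 DSS calls had the same sign in the other treatment. Pnmal2 (1.48) under water, Zfp61 (1.14) and Mill2 (0.90) under DSS and Ccdc61 (-1.07 and -1.16) in both were the remaining named genes. Hddc3, Igsf23, Ccdc61, Myo7a and Slc1a5 passed in all 6 fits that left out 1 library in either treatment, and Vmn2r29 did so under DSS, while the other named genes were each lost in 3 to 6 of those fits. The water count was 8 without LAO1KO replicate B, 9 without DKO replicate A, 8 without DKO replicate B and 9 without DKO replicate C. The DSS count was 6 without LAO1KO replicate A, 7 without DKO replicate B and 6 without DKO replicate C. Red-cell genes had a median of -1.60 over both treatments, 5 of 5 lower when adjusted over the list alone and 0 over all genes (camera adjusted p = 9.16e-09; 0.494 with an estimated correlation). Adipocyte genes had camera adjusted p = 6.03e-07, and 0.925 with an estimated correlation, with Fabp4 at 526 ± 415 CPM in LAO1KO and 102 ± 75.9 in DKO under DSS.

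**Figure D4:**
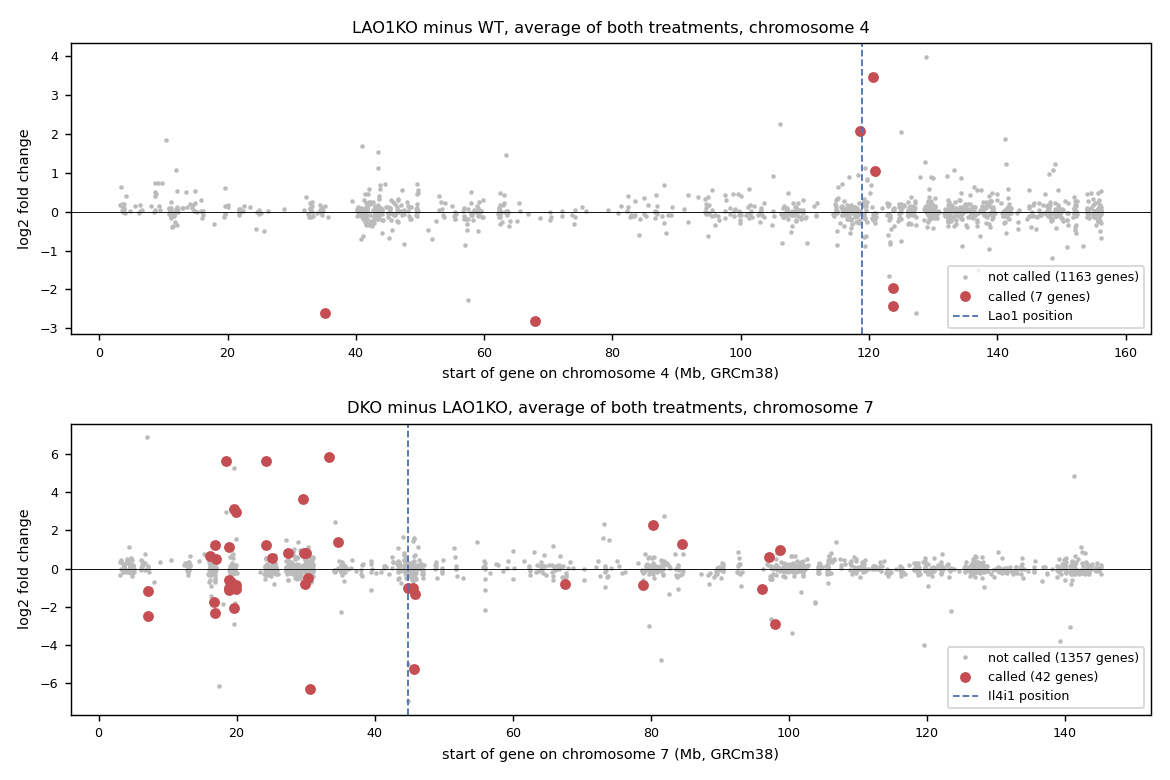
Log2 fold change over both treatments of tested genes by their position in Mb (GRCm38), for LAO1KO against WT on chromosome 4 and DKO against LAO1KO on chromosome 7, with genes that passed in red and dashed lines at Lao1 and Il4i1. Genes that passed between DKO and LAO1KO on chromosome 7 lay from 7.20 to 98.7 Mb on both sides of Il4i1.

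Lists tied to oxidase products gave few changes. Aryl hydrocarbon receptor (AhR) targets respond to indole compounds made from tryptophan. Under DSS averaged over genotypes, 1 of 9 rose, Cyp1b1 (1.15 ± 0.28; edgeR adjusted p = 0.0114), and 1 fell, Xdh (-0.43 ± 0.09; 0.00507), or 2 and 2 when adjusted over the list alone, with camera adjusted p = 0.675. Cyp1a1 was between 0.248 and 0.862 CPM in the group means. No AhR target passed between genotypes in any of the 6 comparisons within treatments, and the lowest camera adjusted p was 0.0459 for DKO against LAO1KO under water, or 0.735 with an estimated correlation. That p was 0.121 without LAO1KO water replicate B, 0.122 without LAO1KO water replicate C, 0.315 without DKO water replicate A and 0.0789 without DKO water replicate C. Aromatic amino acid catabolism had 1 of 17 higher under DSS (Afmid, 0.30) and 2 lower (Ddc, -0.44; Got1, -0.49), or 2 and 2 when adjusted over the list alone, with camera adjusted p = 0.795. Oxidative stress genes had 2 of 20 higher (Gpx4, 0.37; Gclm, 0.27) and 2 lower (Srxn1, -0.54; Gsr, -0.24), or 2 and 3 when adjusted over the list alone, with camera adjusted p = 0.967. Between DKO and WT over both treatments 3 of 20 oxidative stress genes were lower when adjusted over the list alone and 0 over all genes (4.28e-04; 0.636 with an estimated correlation).

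The remaining lists had camera adjusted p above 0.05 for DSS averaged over genotypes. Members that passed included Klf4 (-0.64), Junb (0.43), Ier2 (0.25) and Klf6 (-0.32) of 17 immediate early genes, Cxcl10 of 20 interferon gamma genes (list 0.0536) and Ang4 (1.67) of 16 antimicrobial genes. Tgfa (-0.56) and Ereg (-1.17) passed of 13 epithelial repair genes, and Insig1 (0.74), Fdft1 (0.48) and Mvd (0.45) of 18 cholesterol synthesis genes. Of 16 fatty acid oxidation genes 5 fell, led by Pdk4 (-0.94) and Cpt1a (-0.46; list 0.0523), and of 15 glycolysis and hypoxia genes Ldha (-0.76) and Pgk1 (-0.63) fell. Of 14 stem cell genes Smoc2 (0.37) rose and Cdca7 (-0.46), Axin2 (-0.63) and Ephb2 (-0.35) fell. Of 14 enteroendocrine genes Chga (0.51) and Scg5 (0.82) rose and Gcg (-0.59) fell. Of 10 small intestine genes Apoa4 (2.68), Apoa1 (2.36) and Lct (1.51) rose, with Apoa1 varying from 5.94 to 73.7 CPM between group means. Pdgfra (-0.52) passed of 14 fibroblast genes. No member passed in the ATF4 target, type I interferon, MHC class II, tuft, smooth muscle, endothelial, adipocyte, skeletal muscle, squamous, B cell, plasma cell, T cell, neutrophil, mast cell and eosinophil, or red-cell lists. Exocrine pancreas genes were too few past the count filter to be tested. Over 600 pairs of list and comparison, 157 passed in camera with the preset correlation, 0 with an estimated correlation (lowest adjusted p = 0.150) and 17 in fry.

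DSS responses of different genotypes, which share no library, were correlated across genes, which are not independent replicates. Pearson's r was 0.164 between WT and LAO1KO, 0.0883 between WT and DKO and 0.363 between LAO1KO and DKO, and among genes of at least 10 CPM it was 0.312, 0.210 and 0.694. Spearman's rho was 0.268, 0.216 and 0.532 in the same order. WT and LAO1KO shared 17 lower genes where independent lists would share 2.37. The difference from WT under water and the same difference under DSS correlated at -0.0602 for LAO1KO and 0.156 for DKO, and DKO against LAO1KO at 0.299. Spearman's rho was -0.245, -0.0283 and 0.310 in that order, Pearson's r among genes of at least 10 CPM -0.250, -0.0358 and 0.517, and without chromosomes 4 and 7 -0.0662, 0.0676 and 0.225, so the sign for DKO turned with the measure. LAO1KO and DKO, set against the same WT libraries, correlated at 0.626 under water and 0.677 under DSS. With per-library log CPM differences the observed r was 0.667 and 0.651, where simulated unchanged groups sharing a simulated WT group gave 0.498 and 0.515 over 20 simulations. The covariance was 0.163 and 0.139 against simulated values of 0.0719 and 0.0764, a difference of 0.0911 under water and 0.0627 under DSS. All simulated libraries, WT included, were drawn independently around a common mean per gene, without library-wide shifts such as that of WT water replicate B. The simulations therefore cannot tell a shared genotype effect from such shifts in the WT libraries. The LAO1KO difference under water and the DKO difference under DSS share no library and correlated at -0.0672, and the reverse pair at -0.0306.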

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

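Of the tests in this part, those of distance from Il4i1, of a segment of another strain, of 1 extreme library and both of the clock were chosen only after the result was seen. The others, and the counts over other splits of the libraries, were set before.

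Results below stood out because the DSS response of a knockout differed from that of WT in an interaction test. For DKO against WT 11 genes passed, with interactions of 1.72 for Arntl, 1.74 for Cldn8, 1.22 for Hr, 2.45 for Itpkb, 3.16 for Npy4r, -1.36 for B2m, -2.31 for Mt2, -1.22 for Trim12a and -1.10 for Trim12c. None of these 9 passed in all 12 fits that left out 1 library. Of gene lists with a camera call, the median interactions for DKO were 0.77 for ATF4 targets, 0.38 for the unfolded protein response, 0.46 for heat shock, 0.45 for immediate early genes, -0.89 for interferon gamma, -0.62 for MHC class II and -0.37 for fatty acid oxidation. They were 0.60 for cell cycle, 0.67 for goblet cells, 0.81 for smooth muscle, 1.12 for fibroblasts, 2.64 for adipocytes and -2.32 for mitochondrial mRNA. With an estimated correlation the adjusted p was 0.63 for these lists and 0.285 for mitochondrial mRNA. The DKO interaction without WT water replicate B was 0.35 for ATF4 targets (camera adjusted p = 0.0830) and 0.17 for immediate early genes (0.244), and MHC class II no longer passed (0.0874). Immediate early genes were at 0.24 without DKO water replicate B (0.0887), 0.69 without DKO DSS replicate B and not called without DKO DSS replicate A (0.114). Interferon gamma genes were at -0.57 without WT water replicate A, -0.24 without DKO water replicate A and -0.58 without DKO DSS replicate B. MHC class II also failed without WT water replicate C (0.106), DKO water replicate A (0.0591) or WT DSS replicate A (0.0875). Adipocyte genes were at 1.27 without WT water replicate C (0.238) and 4.04 without WT DSS replicate C, and they failed without DKO water replicate B (0.0914), WT DSS replicate A (0.209) or B (0.0646), or DKO DSS replicate A (0.0683) or C (0.133). For LAO1KO the medians were 0.64 for ATF4 targets, 0.46 for cell cycle, -0.67 for enteroendocrine cells, 0.51 for smooth muscle, 0.84 for fibroblasts, 2.75 for adipocytes, -0.63 for plasma cells and -1.88 for mitochondrial mRNA, each at 0.858 with an estimated correlation. The LAO1KO interaction without WT water replicate B was 0.23 for ATF4 targets (camera adjusted p = 0.232), 0.29 for cell cycle (0.0714) and 0.22 for smooth muscle (0.119), and plasma cell genes no longer passed (0.119). Cell cycle genes were at 0.82 without LAO1KO water replicate A and 0.73 without WT DSS replicate A, and failed without LAO1KO water replicate B (0.0598) or C (0.0523). Smooth muscle genes were at 0.95 without LAO1KO water replicate A, 0.24 without LAO1KO water replicate C (0.222), 0.31 without WT DSS replicate A (0.176) and 0.81 without WT DSS replicate B, and failed without LAO1KO water replicate B (0.0638). Enteroendocrine genes failed without LAO1KO water replicate B (0.0598). Without LAO1KO water replicate C fibroblast genes were at 0.55, plasma cell genes at -0.20 (0.233) and adipocyte genes failed (0.103), and without WT water replicate C adipocyte genes were at 1.35 (0.0634). Plasma cell genes were at -1.01 without WT water replicate A, -1.63 without WT water replicate C, -1.06 without LAO1KO water replicate A, -0.98 without LAO1KO DSS replicate A and -1.63 without LAO1KO DSS replicate B, and failed without WT DSS replicate A (0.0666) or LAO1KO DSS replicate C (0.211). Smooth muscle, fibroblast and adipocyte genes mark layers of the gut wall, and adipocyte scores alone spanned 6.44 log2 units between libraries.

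Genes that passed between DKO and LAO1KO lay almost all on chromosome 7 in edgeR, 42 of 45 over both treatments, against 71 of 90 in DESeq2, 127 of 352 in limma voom and 263 of 2530 in limma voom under DSS. A direct effect of the Il4i1 deletion on its neighbours is argued against by a median distance of 25.2 Mb. For reads moved between near-identical copies, 5 of 42 genes, or 11.9%, share a family name with a gene called in the other direction. The test cannot see a copy that has another name, fell below the count filter or was not called. It therefore does not exclude moved reads. A segment of another mouse strain that travelled with the Il4i1 allele stays open as a candidate explanation. All 18 genes called by edgeR in either treatment, 100%, had the same sign in both. Calls did not fill every bin of 10 Mb. They fell in 6 of 10 bins under water, 6 of 10 under DSS and 7 of 10 in either. For the 42 genes over both treatments it was 9 of 10. The bin left empty there, 50 to 60 Mb, held only 25 tested genes, and 36% of them had an unadjusted p under 0.05. That empty bin therefore does not show a break in the stretch. The bin that holds Il4i1, 40 to 50 Mb, had 4 of 168 tested genes called and 16.7% with an unadjusted p under 0.05. From 10 to 20 Mb it was 16 of 124 and 38.7%. On chromosome 18, which carries neither targeted gene, 10 to 20 Mb had 0 of 33 called but 30.3% with an unadjusted p under 0.05. Low unadjusted p were thus not confined to chromosome 7. The segment cannot be told apart from an effect of the deletion spread over the chromosome, because both come in the same libraries and sequences are not analysed here.

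Mitochondrial mRNA took 32.7% of counts under DSS against 7.87% under water in WT, 19.2% against 12.2% in LAO1KO and 19.5% against 15.7% in DKO, where the exact permutation p was 0.5. A single extreme library as the whole cause is argued against by the difference in WT without WT DSS replicate C, which was 18.6 percentage points. Length bias or RNA degradation may contribute in WT, where log2 fold changes across 17228 nuclear genes fell with transcript length at a Spearman rho of -0.284. The rho was 0.0568 in LAO1KO, -0.0664 in DKO and -0.159 for DSS averaged over genotypes. Under water it was -0.296 for LAO1KO against WT and -0.0707 for DKO against WT. Both use the WT water libraries that the WT response is also set against, so the -0.296 is not a separate recurrence of the trend. More mitochondria per cell stays open, since nuclear-encoded respiratory chain genes had a median of 0.30 in WT with 75 of 96 above 0, a median that decides nothing because it lies at the 0.3 the test required.

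Clock genes moved in opposite directions under DSS. Medians of the Dbp-phase genes exceeded those of the Arntl-phase genes by 3.33 in WT, 1.90 in LAO1KO and 0.638 in DKO, the smallest of the 3. Collection of the DSS and water mice at different times of day is a candidate explanation that predicts this, and an effect of DSS on the clock predicts the same, so these data cannot separate them and no collection time is given. A general loss of depth or quality in the DSS libraries predicts that both gene sets fall together. Their difference within genotypes was 1.97 (exact permutation p = 0.00025, the smallest possible). Because the test was chosen after the sets were seen to move apart, this p is not independent evidence. Nor does it address effects of quality on other genes. The clock index of DKO minus WT was 1.09 under water and -1.06 under DSS (exact permutation p = 0.1 each, the smallest possible).

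Other splits of the same libraries were counted to see whether grouping by chance gives as many genes, the real split included. Between groups of 3 there are 10 splits, too few for a share under 0.05. The real counts and the highest of the other splits were 10 and 339 for LAO1KO against WT under water, where 2 splits reached the real count, and 117 and 0 for DKO against WT, 15 and 0 for DKO against LAO1KO under water, with 1 split each. They were 16 and 0, 48 and 1, and 12 and 0 for the same comparisons under DSS, and 2428 and 0, 37 and 4, and 3 and 1 for DSS in WT, LAO1KO and DKO, again with 1 split each. The split with 339 genes exchanged WT replicates A and B with LAO1KO replicates B and C, which points to a structure of those samples other than genotype. Over 100 splits drawn within strata, a share under 0.05 reached the real count for DSS averaged over genotypes (2996 genes, highest other 212, 1 split). The same held for DKO against WT (106, 19, 1 split) and DKO against LAO1KO (45, 3, 1 split). It held too for LAO1KO against WT (25, 45, 2 splits) and the DKO interaction (11, 19, 3 splits), though another split there called more genes. Labels were exchanged separately within each stratum, so a mixed split carries real group differences into its spread or its interaction. These shares therefore do not exclude chance. For the LAO1KO interaction all 100 splits gave at least the real count of 0, with up to 293.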

How the results depend on the processing

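The fits without mitochondrial and ribosomal RNA genes, with voom's library weights, without chromosomes 4 and 7 and without WT water replicate B and WT DSS replicate C together were chosen after the data were seen, and the other alternatives before. Counts of genes are compared with the reported ones, and where a change comes from fewer genes or libraries the alternative's construction shows it. For the others the cause was not tested.

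DESeq2 called more genes between genotypes, with 300, 782 and 48 under water for LAO1KO against WT, DKO against WT and DKO against LAO1KO, 56, 147 and 26 under DSS and 48, 210 and 91 over both. It called 707 for DSS in LAO1KO, 181 in DKO, and 438 and 492 for the LAO1KO and DKO interactions. Voom with library weights called 933, 213 and 32 under water, 967, 459 and 2530 under DSS and 100, 274 and 352 over both. It called 4990 for DSS in LAO1KO, 478 in DKO, 6179 averaged over genotypes, and 2324 and 235 for the interactions.

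A fit on only the libraries compared called 4, 32 and 4 genes under water, 1083 for DSS in WT, 0 in LAO1KO (37 in edgeR as reported, with 2936 unadjusted), 33 in DKO and 6 for the DKO interaction. Without WT water replicate B and WT DSS replicate C together, 18 and 52 genes passed for LAO1KO and DKO against WT under water, 231 for DSS in WT, 154 in LAO1KO, 27 in DKO and 0 for the DKO interaction. Without genes of chromosomes 4 and 7, 5, 21 and 0 passed under water, 17 for DKO against WT and 0 for DKO against LAO1KO under DSS, 16, 29 and 0 over both, and 1 for the LAO1KO interaction.

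RLE scaling gave 70 genes for DSS in LAO1KO, no count filter 60, and leaving out mitochondrial and ribosomal RNA 77. With no count filter 13 passed for DSS in DKO and 2 for the LAO1KO interaction. Higher and lower calls of the DKO interaction were 11 and 5 under RLE scaling and without mitochondrial and ribosomal RNA, against 6 and 5 as reported, and those of DKO against WT under water were 51 and 59 without mitochondrial and ribosomal RNA, against 70 and 47.

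The labels do not say whether libraries with the same replicate letter share a litter, day or batch. Libraries with the same letter in different groups correlated at a median of 0.0271 (from -0.299 to 0.319 over 45 pairs). With different letters the median was -0.0245 (from -0.299 to 0.394 over 90 pairs), and 8 of 18 libraries were closest to their own letter. A batch shared by letter is therefore not excluded. With the letter as a replicate block, 178 genes passed for DKO against WT under water, 131 for DSS in LAO1KO, 6 in DKO, and 1 and 35 for the interactions. The block moved no other count by more than 1.5 times and lost no list call.

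Leaving out 1 library at a time gave 5 to 105 genes for LAO1KO against WT under water, 30 to 387 for DKO against WT and 8 to 12 for DKO against LAO1KO. Under DSS it gave 9 to 16, 24 to 40 and 6 to 12. It gave 777 to 2702 for DSS in WT, 1 to 346 in LAO1KO, 1 to 2 in DKO, 1928 to 3551 averaged, 0 to 47 for the LAO1KO interaction and 0 to 148 for the DKO interaction. Over both treatments it gave 17 to 30, 74 to 105 and 32 to 54.

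Results that reversed were Retn under voom (1.96 for DKO against LAO1KO under water), Slc37a2 for LAO1KO against WT under DSS without WT DSS replicate C (0.88, also without both libraries; -2.18 to 0.88 over left-out libraries) and ATP6 for LAO1KO against WT over both treatments without WT DSS replicate C (-0.39 to 0.0238). The mitochondrial list of that last comparison reversed at adjusted p = 0.722 without WT DSS replicate C and 0.998 without both libraries, with 1.02e-04 as its lowest without another library. Among genes of at least 10 CPM, DSS responses correlated at 0.312 between WT and LAO1KO, 0.210 between WT and DKO and 0.694 between LAO1KO and DKO. Among them the correlation between DKO against WT under water and under DSS was -0.0358, against 0.156 over all genes, and it was -0.250 for LAO1KO against WT and 0.517 for DKO against LAO1KO. For LAO1KO and DKO against the same WT it was 0.717 under water and 0.723 under DSS, and for the crossed pairs -0.336 and -0.231.

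Of the 157 list calls 0 passed with an estimated correlation and 17 pairs passed in fry, of which 10 were among the 157. Under RLE scaling 156 kept their call. Of the named genes' results 790 kept their side of the threshold under RLE scaling, 1 passed newly and 2 were lost, and under DESeq2 668 were the same and 106 passed newly. Depth limits what can be said of Lao1, at 0 to 10 counts per library.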

Other observations

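The tests for genes gathering on single chromosomes and the comparison of composition between libraries in this part were chosen after the results had been seen. On chromosome 4 the genes that passed between LAO1KO and WT over both treatments lay from 35.2 to 124 Mb, at a median distance of 4.75 Mb from Lao1, and 1 of the 7 lay within 1 Mb. Between DKO and LAO1KO no gene of chromosome 4 passed in edgeR over both treatments, among 1170 tested there. Several of the largest differences that both knockouts showed against WT lay on neither chromosome, such as Mier3 on chromosome 13 and Pcsk5 on chromosome 19. Ndufs5-ps on chromosome 16 was at 2.62 CPM in WT and 152 in LAO1KO under water.

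WT water replicate B had the lowest score of all 18 libraries for the small intestine (2.60), plasma cell (-1.18), T cell (-1.66), mast cell and eosinophil (-2.32) and red-cell genes (2.42), each as mean log2 CPM. It was also lowest for AhR targets (2.82), aromatic amino acid catabolism (3.52), antimicrobial (3.51), clock (3.81), fatty acid oxidation (5.73) and mitochondrial mRNA (11.2). It had the highest score for ATF4 targets (4.18), the unfolded protein response (6.87), immediate early (5.44), type I interferon (4.85), cholesterol synthesis (6.69), glycolysis and hypoxia (6.70), cell cycle (5.27), smooth muscle (8.96) and fibroblast genes (6.44). B-cell scores ranged from -2.21 to 2.25 between LAO1KO DSS replicates C and B. Ribosomal RNA was 4.65% of counts in LAO1KO DSS replicate B and 6.50% in replicate C, against 1.80% in replicate A. Voom's weights per library ran from 0.187 for LAO1KO water replicate A to 6.27 for LAO1KO DSS replicate A.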
